A study of Mus musculus with 2 samples.

How the data were processed

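H3K4me2 ChIP-seq peaks were taken as deposited for 2 biological replicates of mouse embryonic facial prominence at embryonic day 12.5, pools of 120 and 88 embryos. The 4 deposited peak lists were those of replicate 1, replicate 2, both replicates pooled, and the replicated list. Per the file headers and accompanying text, the authors aligned reads to mm10 and called peaks on each replicate and on the pooled replicates, each with further input files whose role is not given. The replicated list derives from the pooled list and both replicate lists. The caller, its version and the rule behind the replicated list are not given in the sources used here. The other values used were the deposited positions, the start and end of each peak in bases on mm10, with starts counted from 0. The deposited peak scores were −log10 p and −log10 q, each scaled by the authors within its own list and never below 2 for −log10 p. They were used only to rank, describe or filter peaks within a list and never compared between lists as a measure of signal. The files hold no read counts, so depth is unknown and no interval on read sampling was given.

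Positions were checked against GRCm38, and 0 peaks ran past a chromosome end. Analyses used chromosomes 1 to 19, X and Y, and peaks on unplaced scaffolds are given apart. Genes were the 21853 protein-coding genes of GENCODE release M21 on these chromosomes, with 54361 TSSs of protein-coding transcripts. A gene counted as marked when a peak overlapped the 1 kb on either side of any of its TSSs. Coverage was the number of bases under peaks within 5 kb of the TSS with the most covered bases (a window of 10001 bases). All peaks in the window counted, those at neighbouring genes included. Distal peaks lay more than 1 kb from every protein-coding TSS and were assigned to the gene of the nearest TSS within 100 kb. Peak location followed the peak midpoint, with the first that applied of promoter (1 kb), exon, intron and intergenic. The CpG observed/expected ratio was computed within 500 bases of each TSS. The highest ratio over the TSSs of a gene was used, and genes were split into 3 equal classes. Domains were replicated peaks joined over gaps of at most 1 kb.

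Replicates were compared by the share of peaks overlapped over at least 50% of either peak, and by the base-pair Jaccard index, with 100 random rotations of the peaks along each chromosome as the chance level. The 19 gene lists were fixed before the data were examined: facial mesenchyme transcription factors, craniofacial signalling, surface and oral epithelium, cartilage, bone, skeletal muscle, endothelium, erythroid, macrophage and leukocyte, neuron, glia and Schwann cell, forebrain and eye, heart, liver, germ line, Hox paralogue groups 1 to 4, Hox groups 5 to 13, ribosomal proteins and olfactory receptors. The erythroid gene Ahsp had no protein-coding gene of that symbol in the annotation and was left out. Each list's value was placed among those of 10000 random lists of the same size (random lists tied with it counted at 50%), with bounds that left 2.5% of the random lists on either side. Exact binomial and Wilson intervals have a confidence level of 95% and cover counting error only. No test was made between samples, since there was 1 group.

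The named genes followed a rule fixed before the data were examined. It took the genes of the 25 domains with the most covered bases that hold a protein-coding TSS and are at least 50% covered in each replicate. It also took, in each list, up to 4 members with the most covered bases and up to 4 without a peak, in list order. Further, it took the 5 genes with the most covered bases among replicate-specific promoters in each direction, every Hox gene, the mapped loci (Msx1, Dlx5 and Dlx6, Alx1, Prrx1 and the Hoxa cluster), and the 5 widest domains with no protein-coding TSS within 1 kb. Cd68 and the genes with the most distal peaks were chosen after their values were seen.

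The percentile method was tested on random lists of the 21853 genes, with values from the real replicated peaks. Of 550 unchanged lists, 4% were outside the bounds for marking, 5.64% for coverage and 2.55% for distal peaks. These lists were drawn as the reference lists were, so the rates check the procedure and not its use on chosen lists. With 2000 bases added per gene 92.7% of 550 lists were called for coverage, with 3 distal peaks added per gene 100%, and with every peak removed 100%. In the last case the share was 0 whatever list was drawn, so that rate was fixed by the random lists and measures no detection. Of 50 lists of CpG-rich genes, 84% were called for coverage against unmatched random lists and 4% against CpG-matched lists. In a comparison with bedtools on simulated peaks, 5 of 5 quantities were equal. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and pysam 0.24.0, samtools 1.23.1 and bedtools 2.31.1.

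Alternatives were peaks with −log10 p of at least 5 or −log10 q of at least 2, an overlap of at least 1 base or of at least 50% of both peaks, the same number of peaks from each replicate (44190), promoter windows of 500 bp and 2.5 kb, coverage windows of 2.5 kb and 10 kb, a reach of 50 kb and 250 kb, only the 5′-most TSS of each gene, the list of either replicate or the pooled list in place of the replicated list, random lists matched on 10 classes of the CpG ratio, and joining gaps of 0 bases and 3 kb. For the gene lists, a further alternative kept only replicated peaks that both replicates hold. Text files that describe the peak files were read for their descriptions and hold no measurements.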

Results

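The series profiled H3K4me2, dimethylation of lysine 4 of histone H3, a mark of promoters and enhancers, by chromatin immunoprecipitation and sequencing (ChIP-seq) in the embryonic facial prominence of mice of strain B6NCrl at embryonic day 12.5. There was 1 group with 2 biological replicates, a pool of 120 embryos (replicate 1) and a pool of 88 embryos (replicate 2), each of mixed sex. The design therefore held no comparison between conditions, and the values below compare the replicates and describe where the peaks lay. On chromosomes 1 to 19, X and Y, replicate 1 had 50084 peaks covering 47.7 Mb and replicate 2 had 44190 peaks covering 46.0 Mb, a mean of 47137 ± 4168 peaks and 46.9 ± 1.22 Mb (SD, n = 2). The pooled reads of both replicates gave 51153 peaks (53.5 Mb), and the replicated list, a subset of the pooled peaks, held 35330 (49.5 Mb). The peak files hold no read counts, so the depth of each library is unknown. With 2 samples of 1 group no test between samples was possible, and the SD measures only the spread between these pools.

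Many of the widest H3K4me2 domains lay over genes of craniofacial development. The domain with the most covered bases held Tbx3, a T-box transcription factor gene of limb and craniofacial development, and spanned 119660858 to 119688214 on chromosome 5 (mm10), with 25476 bases under replicated peaks and 24187 ± 38.2 bases under the peaks of each replicate (SD, n = 2). The domain of Nr2f2, which encodes an orphan nuclear receptor, followed at 70345348 to 70371199 on chromosome 7, with 25046 bases (replicates 24513 ± 208). Those of Ebf3 (24126 bases, replicates 22942 ± 124), Zfhx3 (23953 bases, replicates 22561 ± 335) and the TALE homeobox gene Meis2 (22378 bases, replicates 21145 ± 17.0) came next. The adjacent genes Dlx1 and Dlx2, homeobox genes that pattern the jaw, shared a domain at 71524874 to 71547325 on chromosome 2 with 21186 bases (replicates 20495.5 ± 139). Pou3f3 (20535 bases), the Hedgehog receptor gene Ptch1 (19424 bases, replicates 18850.5 ± 72.8), Bahcc1 (18705 bases) and Tbx2 (17587 bases, replicates 17123 ± 368) completed the first 10.

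The question behind this ranking was which genes lay in the 25 widest domains with a protein-coding transcription start site (TSS), out of 13667 such domains. These 25 domains covered 14.3 to 25.5 kb each and named 28 genes. Of the domains, 10 held a gene of the list of facial mesenchyme transcription factors, 2 a gene of the craniofacial signalling list (Ptch1 and Wnt5a) and 1 a gene of another list, that of Hoxa1 and Hoxa2. Beside those above, they held Six1, Mn1, Six2, Nr2f1, Zfhx4, Satb2, Dlx6, Tnrc18, Smad7, Tfap2a, Kdm6b, Meis1, and the neighbours Rhof and Setd1b. Six1 and Six2 are homeobox genes of head mesenchyme, Satb2 is a gene of palate and jaw development, and Kdm6b encodes a histone H3 demethylase. The membership depended on how peaks were joined: of the genes named with gaps of at most 1 kb, 11 were also named when peaks were not joined, and 20 with gaps of at most 3 kb.

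At the facial genes chosen in advance for mapping, the peaks formed blocks over the gene starts. The homeobox gene Msx1 (chromosome 5, 37820485 to 37824583) lay within a pair of adjoining replicated peaks, and 12.6 kb of the 54.1 kb mapped were covered. Around Dlx5 and Dlx6, paired homeobox genes of lower jaw identity, 26.3 kb of 68.8 kb were covered by 7 replicated peaks, with 24.7 kb in replicate 1 and 24.6 kb in replicate 2. Around Alx1, a homeobox gene of the frontonasal region, 12.5 kb of 81.5 kb were covered by 11 replicated peaks. Around Prrx1, a homeobox gene of mesenchyme, the value was 13.6 kb of 119 kb.

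**Figure D1:**
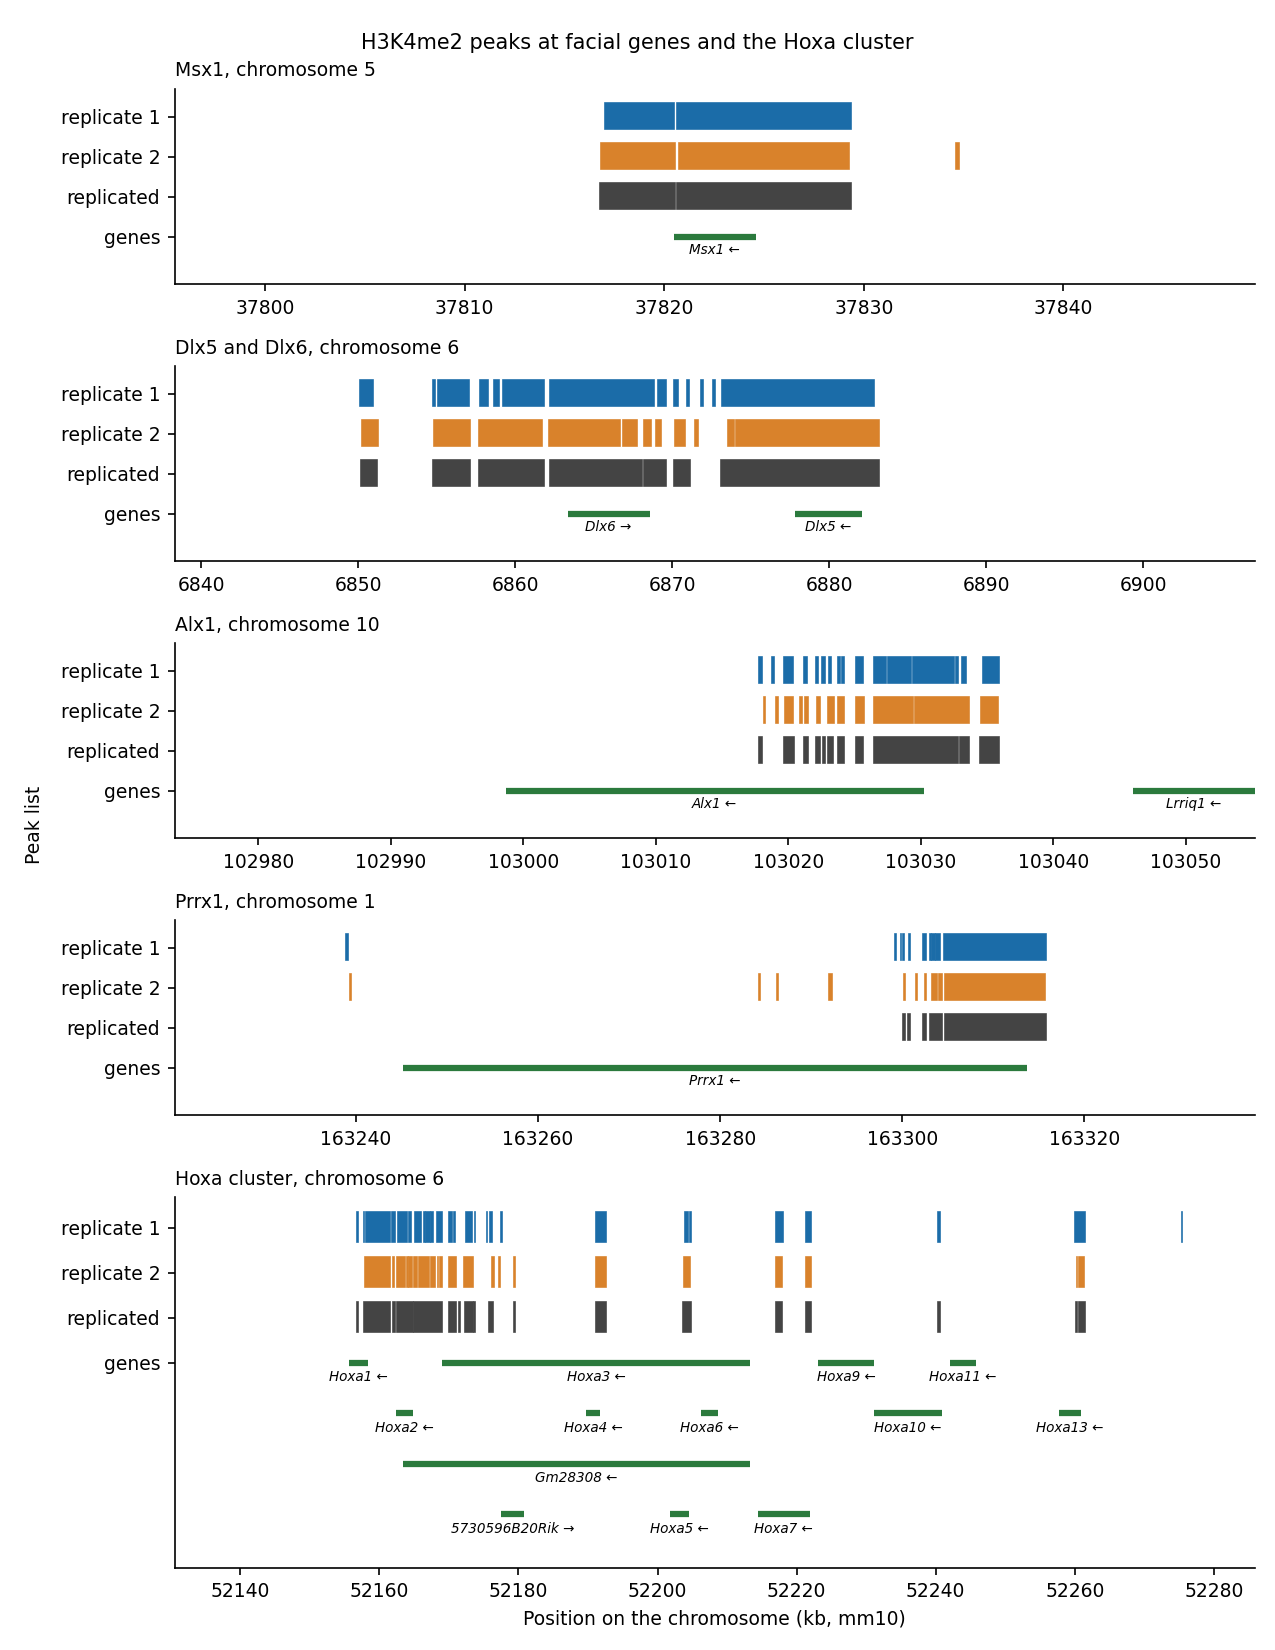
Peaks of replicate 1 (blue), replicate 2 (orange) and the replicated list (grey) are drawn to scale over protein-coding genes (green, arrows give the strand) at the facial genes and the Hoxa cluster, with position on the chromosome in kb (mm10) on the x axis and the peak list on the y axis. Covered lengths in the replicated list were 12.6 kb at Msx1, 26.3 kb at Dlx5 and Dlx6, 12.5 kb at Alx1, 13.6 kb at Prrx1 and 21.8 kb at the Hoxa cluster with its flanks.

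The next question was how widely the genes of each cell type or tissue list were marked. All 45 facial mesenchyme transcription factor genes had a replicated peak within 1 kb of a TSS (100%, exact 95% interval 92.1% to 100%), in the replicated list and in each replicate. Their median coverage within 5 kb of the TSS was 8158 bases of a window of 10001 (replicates 7600.5 ± 221, SD, n = 2), against 1906 bases over all 21853 protein-coding genes. Six2 was covered over the whole window in the replicated list and in both replicates (10001 bases, replicates 10001 ± 0). Tbx3 had 9950 bases (replicates 9736.5 ± 12.02), Gsc, a homeobox gene of jaw mesenchyme, had 9893 (9198 ± 223), and Nr2f2 had 9799 (9646.5 ± 231). All 30 craniofacial signalling genes also had a peak, with a median of 5612 bases (replicates 5460 ± 153). Among them Ptch1 (replicates 9929.5 ± 7.78) and the ligand gene Wnt5a (replicates 9731 ± 382) were covered over 10001 bases, the growth factor receptor gene Pdgfra over 9865 (9757.5 ± 36.1), and Lef1, a nuclear effector of Wnt signalling, over 9467 (8898 ± 113). The median number of distal peaks, those over 1 kb from any protein-coding TSS with a TSS of the gene as the nearest within 100 kb, was 5 per facial transcription factor gene (replicates 7.5 ± 0.707) and 3 per signalling gene (replicates 4 ± 0), against 0 over all genes. Tbx3 had 17 distal replicated peaks (22 in replicate 1 and 21 in replicate 2), Nr2f2 12 (23 and 12) and Lef1 8 (12 and 14).

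Of the surface and oral epithelium genes, 22 of 25 had a peak, with a median of 2533 bases (replicates 2350 ± 130). Cldn6, a tight junction gene, was covered over 8622 bases, the homeobox gene Pitx2 over 8077, Tfap2c over 6224 and Sox2 over 6077, whereas the keratin genes Krt5, Krt14 and Krt15 had no replicated peak within 1 kb of a TSS (Krt5 had a peak in replicate 1 alone). Of the cartilage genes, 13 of 15 had a peak, with a median of 2921 bases (replicates 2697 ± 53.7). Sox6 (7423 bases) and Sox5 (5853 bases), transcription factor genes of cartilage formation, and the collagen genes Col2a1 (6048 bases) and Col11a1 (4110 bases) were the widest, and Matn1 and Snorc had no peak within 1 kb. Of the bone genes 5 of 12 had a peak (median 900 bases, replicates 827.5 ± 116): Runx2, the transcription factor gene of osteoblast commitment, had 6791 bases, Col1a1 4928, Sp7 4902 and Col1a2 4816, and the matrix genes Ibsp, Bglap, Spp1 and Dmp1 had none within 1 kb. Of the skeletal muscle genes 10 of 18 had a peak (median 1154.5 bases, replicates 1065.5 ± 75.7). Pax7, a gene of muscle progenitors and neural crest, had 6748 bases, Lbx1 3946, Msc 1985 and Myod1 1746, and the contractile genes Myh3, Myh8, Actc1 and Acta1 had no peak within 1 kb.

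Vascular and blood cell genes were marked in part, and macrophage genes had no peak at a TSS. Of the endothelium genes 10 of 16 had a peak (12 in replicate 1 and 10 in replicate 2), with a median of 1844 bases (replicates 1873 ± 222). The transcription factor genes Fli1 (9312 bases), Erg (3661 bases) and Sox17 (3007 bases) and the adhesion gene Esam (3421 bases) were covered, and Pecam1, Cdh5, Tek and Tie1 had no replicated peak within 1 kb of a TSS (Pecam1 had a peak in replicate 1 alone). Of the erythroid genes 5 of 14 had a peak, with a median of 0 bases (replicates 138.5 ± 196). Tal1 was covered over 4154 bases, the erythropoietin receptor gene Epor over 2698, Ank1 over 1968 and Klf1 over 1910, while Gata1, Alas2, Slc4a1 and Spta1 had no replicated peak within 1 kb (Slc4a1 had a peak in replicate 1 alone). Of the 15 macrophage and leukocyte genes, 0 had a peak within 1 kb in any of the replicated list and both replicates (exact 95% interval 0% to 21.8%), with a median of 0 bases (replicates 0 ± 0). Csf1r, Ptprc and Cx3cr1 had no covered base within 5 kb, whereas Spi1 had 1393 and Cd68 had 4004 under peaks more than 1 kb from their own TSS.

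Nerve and glial genes were mostly marked. Of the neuron genes 17 of 18 had a peak, with a median of 2711 bases (replicates 2555 ± 20.9). Isl1, a homeobox gene of sensory and motor neurons, had 6151 bases, the growth cone gene Gap43 5130, the tubulin gene Tubb3 4557 and the neurotrophin receptor gene Ntrk2 4464. Phox2b had no peak within 1 kb. Of the glia and Schwann cell genes 9 of 10 had a peak, with a median of 1646.5 bases (replicates 1547.5 ± 199). Sox10 had 4987 bases, Erbb3 4610, Foxd3 3675 and Ngfr 3497, and the myelin gene Plp1 had none.

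Lists named after other tissues or gene classes differed from each other. Of the forebrain and eye genes 15 of 18 had a peak, with a median of 2120 bases (replicates 2073.5 ± 488) and 4 distal peaks per gene (replicates 4.75 ± 1.06). The homeobox genes Emx2 (9610 bases), Six3 (8651 bases), Otx1 (7988 bases) and Lhx2 (7708 bases) were the widest, and the differentiation genes Neurod6, Crx and Cryaa had no peak within 1 kb. Of the heart genes 7 of 12 had a peak (9 in replicate 1 and 8 in replicate 2), with a median of 1609 bases (replicates 1172 ± 136). Tnni3 had 3554 bases, Tbx20 3192, Hcn4 3145 and Irx4 2941, and Myh6, Myl7, Myl2 and Nppa had no replicated peak within 1 kb, although 2083 bases were covered within 5 kb of Myl7. Myh6 had a peak within 1 kb in replicate 2 alone and Myl2 in replicate 1 alone. Of the liver genes 3 of 16 had a peak, namely Apoh (3358 bases), Foxa3 (2789 bases) and Apoa1 (1558 bases, with no peak within 1 kb in replicate 1), with a median of 0 bases (replicates 0 ± 0). Alb, Afp, Apoa2 and Apob had no replicated peak within 1 kb (Apob had a peak in replicate 1 alone), although 2484 bases were covered within 5 kb of Apoa2. Of the germ line genes 2 of 14 had a peak, Tdrd1 (2329 bases) and Dazl (840 bases), with a median of 0 bases (replicates 0 ± 0), and Ddx4, Sycp1, Sycp3 and Stra8 had none. Of the ribosomal protein genes, taken by a symbol pattern as genes active in all cells, 76 of 79 had a peak, with a median of 3078 bases (replicates 2931.5 ± 20.5). Rpl13a (6700 bases), Rpl35 (6473 bases), Rpl18 (6111 bases) and Rps2 (6005 bases) were the widest. Peaks at neighbouring genes count in these values, as at Rpl13a, where the adjacent Rps11 starts within 5 kb. Their part was weighed only for the facial transcription factors. The 3 without a peak within 1 kb were Rpl10l, Rpl39l and Rpl3l, whose symbols the pattern also matched, although 1941 bases were covered within 5 kb of Rpl3l. Whether these 3 genes are active in all cells was not tested. Of the olfactory receptor genes, chosen as genes silent outside sensory neurons, 5 of 1134 had a peak (0.441%), with a median of 0 bases (replicates 0 ± 0). Those with the most covered bases were Olfr94 (1354 bases) and Olfr56 (746 bases).

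**Figure D2:**
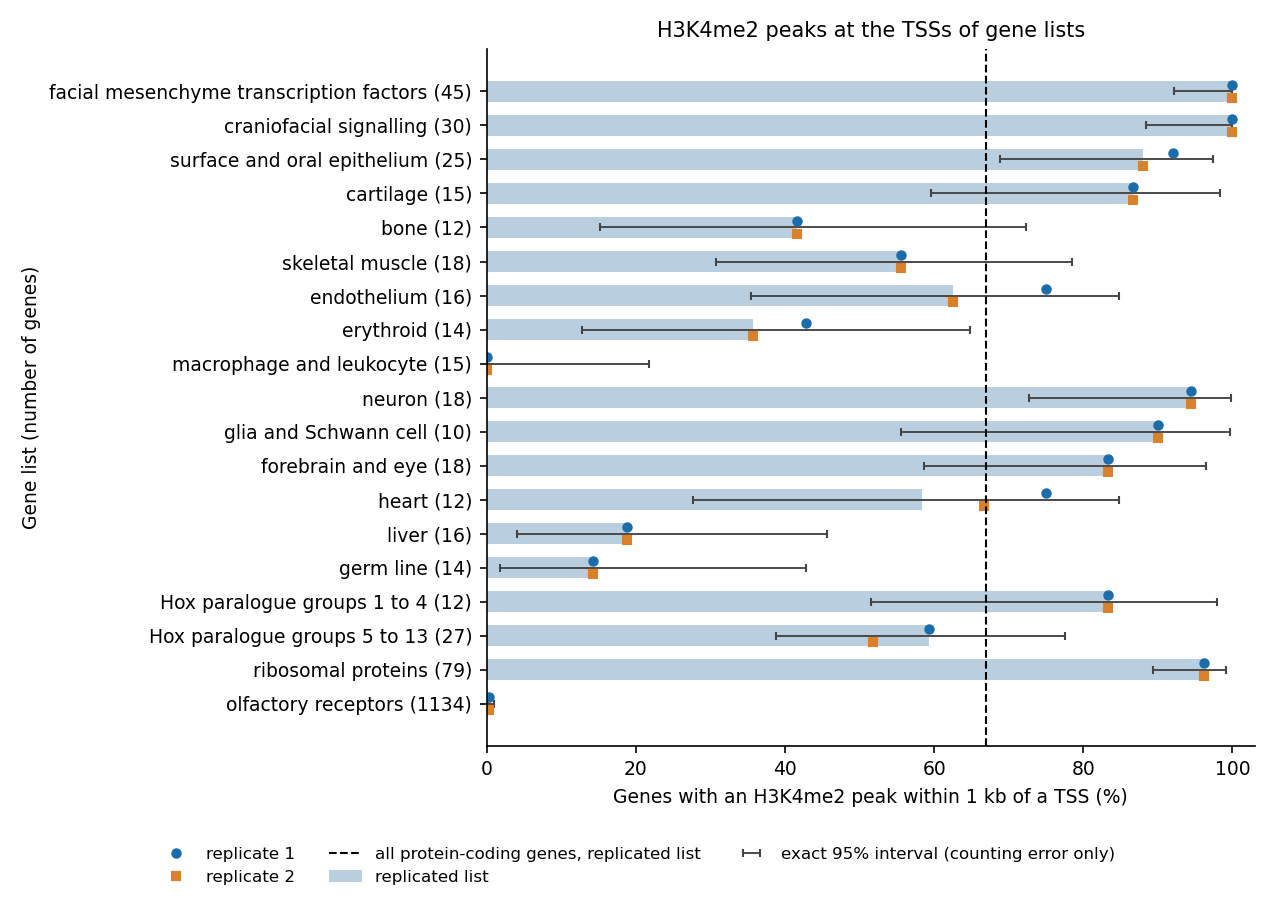
The percentage of genes of each list with a peak within 1 kb of a TSS is on the x axis for the replicated list (bars) and each replicate (points), with the exact 95% interval of the replicated value as a whisker and the share of all protein-coding genes as a dashed line. All 45 facial mesenchyme transcription factor genes and 0 of 15 macrophage and leukocyte genes had a peak, beside 67.0% of all genes.

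Each list was set against 10000 random lists of as many protein-coding genes, and the percentile of the list's value was read against bounds that left 2.5% of the random lists on either side. The share of marked genes lay above the bounds for facial transcription factors (percentile 100), signalling (100), epithelium (99.0), neuron (99.6) and ribosomal proteins (100). It lay below them for the erythroid (1.11), macrophage (0), liver (0), germ line (0.005) and olfactory receptor (0) lists, so that 10 of 19 lists were outside, where 0.95 would be by chance. Cartilage (94.6), glia (93.2), forebrain and eye (93.1), Hox paralogue groups 1 to 4 (88.4), endothelium (34.8), heart (26.9), Hox groups 5 to 13 (20.2), skeletal muscle (15.7) and bone (4.09) lay within. For median coverage, 8 lists were outside: facial transcription factors (100), signalling (100), cartilage (98.2) and ribosomal proteins (100) above, and liver (1.37), erythroid (1.59), germ line (1.59) and olfactory receptors (0) below. The liver, erythroid and germ line calls rest on counting ties at 50%, since 2.73%, 3.18% and 3.18% of the random lists also had a median of 0. Neuron (97.3), epithelium (95.4), forebrain and eye (69.9), endothelium (46.4), Hox groups 1 to 4 (42.5), glia (37.1), heart (34.3), bone (13.5), muscle (12.96), Hox groups 5 to 13 (5.79) and macrophage (2.56) lay within. Genes are not replicates, so these percentiles describe these libraries and carry no p-value.

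**Figure D3:**
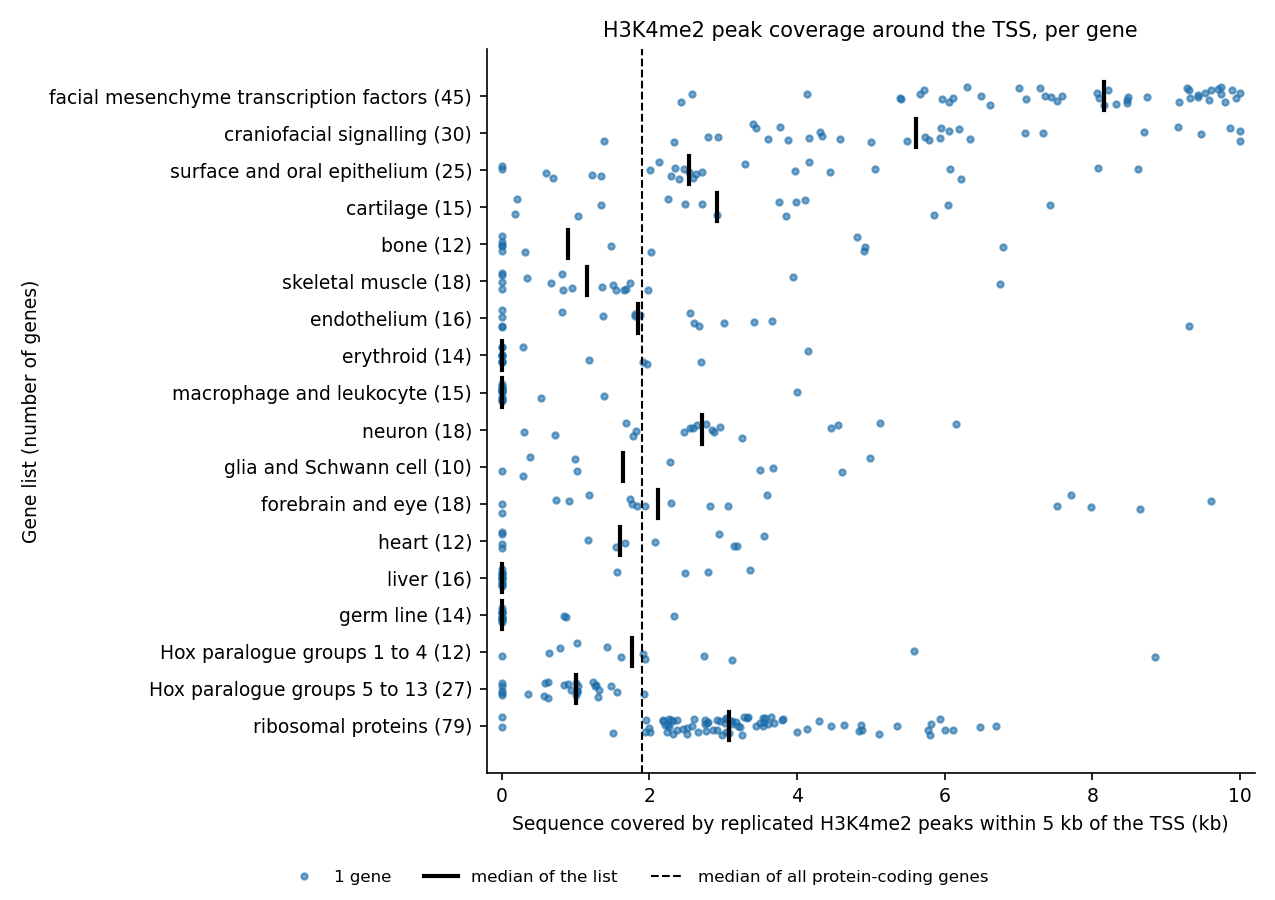
Each point is a gene of the list on the y axis (olfactory receptors not drawn), with the sequence covered by replicated peaks within 5 kb of its TSS on the x axis in kb, solid marks for the median of each list and a dashed line for that of all protein-coding genes. The facial mesenchyme transcription factors had a median of 8158 bases, the ribosomal proteins 3078 and the macrophage and leukocyte genes 0, beside 1906 for all genes.

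Promoter CpG content moved with these values, and random lists matched on the CpG observed/expected ratio changed several calls. The facial transcription factors stayed above the bounds for coverage (percentile 100), as did signalling (100). For marking, the facial list lay at 98.5, a call that rests on counting ties at 50%, since its share of 100% is the highest possible. Marking of the signalling list, also at 100%, came to 94.6. So many of its matched lists tied with it that no share could have passed, so this percentile decides nothing. For marking, epithelium (92.3) and neuron (92.0) then lay within the bounds. Ribosomal proteins, unmarked only at Rpl10l, Rpl39l and Rpl3l, turned to 11.97 and the erythroid list to 85.4, whereas cartilage (99.8) and glia (99.98) lay above and Hox groups 5 to 13 (0) below. The liver (2.24), germ line (0) and olfactory (0) lists stayed below for marking. The macrophage list lay at 2.07 with ties counted at 50%, but 4.14% of its matched lists also had no marked gene. For coverage, germ line (0.015) stayed below. The liver, erythroid and olfactory receptor medians of 0 tied with 56.1%, 94.5% and 100% of their matched lists, so matching decided nothing on their coverage. Some calls also depended on single replicates: without replicate 2, 42.9% of erythroid genes were marked (percentile 3.07) and the median coverage was 277 bases (4.15), and without replicate 1 the cartilage coverage of 2659 bases lay at 97.2 and the neuron coverage of 2569.5 bases at the upper bound. Macrophage coverage was below the bounds without replicate 1 (2.38) and without replicate 2 (2.17), with ties at a median of 0 counted at 50%. Windows, start sites and the list used changed further calls: epithelium marking with 500 bp (97.2), cartilage coverage at the 5′-most TSS (96.7), and coverage with a window of 10 kb for erythroid (2.55) and germ line (3.16) genes came within the bounds, as did erythroid marking (2.8) and coverage (2.97) with the pooled list and cartilage coverage with only replicated peaks that both replicates hold (96.1). Heart marking at the 5′-most TSS (33.3%, percentile 1.85) lay below the bounds, and forebrain and eye coverage with 10 kb (99.3) and neuron coverage with the pooled list (97.6) or the 5′-most TSS (98) above.

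The Hox genes, which mark axial level and are silent in the most anterior neural crest, were covered unevenly, with the most bases at Hoxa1 and Hoxa2. The Hoxa cluster (chromosome 6, 52155590 to 52260880) was covered over 20.2% of its length (replicates 17.5% ± 0.114, SD, n = 2) and the Hoxd cluster (chromosome 2, 74668310 to 74765142) over 14.0% (replicates 12.9% ± 0.494). The Hoxb cluster (chromosome 11, 96194316 to 96368256) was covered over 6.47% (replicates 5.44% ± 1.21) and the Hoxc cluster (chromosome 15, 102921103 to 103036852) over 4.50% (replicates 3.81% ± 0.339; 2.90% with only peaks of −log10 p of at least 5). Of paralogue groups 1 to 4, 10 of 12 genes had a peak, with a median of 1763.5 bases (replicates 1537 ± 15.9). Hoxa2, the gene of second arch identity, was covered over 8848 bases (replicates 7554.5 ± 436) and Hoxa1 over 5591 (5254 ± 263), in a shared domain. Hoxb2 had 3114 bases and Hoxb3 2737, the latter with 1503 bases in replicate 1 and 1963 in replicate 2, and a peak within 1 kb in replicate 2 but not in replicate 1. Hoxd1 had 1947 bases, Hoxd3 1911, Hoxa4 1616, Hoxb4 1431 (1548 in replicate 1 and 932 in replicate 2), Hoxc4 791 (470 and 865) and Hoxd4 645. Hoxb1 had a peak within 1 kb in replicate 1 alone (215 bases) and no replicated peak, and Hoxa3, whose annotation overlaps that of Gm28308, had no peak within 1 kb. Replicated peaks did lie elsewhere in the annotated span of Hoxa3 (52169062 to 52213336), such as 52172195 to 52173400, so only its annotated TSSs lacked a peak.

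Of Hox paralogue groups 5 to 13, 16 of 27 genes had a peak (16 in replicate 1 and 14 in replicate 2), with a median of 1008 bases (replicates 706.5 ± 17.7). The widest were Hoxa7 (1931 bases, replicates 1922 ± 66.5), Hoxd13 (1560 bases, 1495.5 ± 4.95), Hoxd8 (1479 bases) and Hoxd9 (1326 bases). Hoxa13 had 1309 bases, Hoxc13 1280, Hoxd11 1272, Hoxa5 1232, Hoxc5 1019, Hoxb7 1016, Hoxb5 and Hoxb6 1008 each, Hoxb9 847, Hoxd10 630, Hoxc10 575 and Hoxa10 357. By replicate, the values were 957 and 721 at Hoxc13 and 719 and 1005 at Hoxa5, and the replicates differed by over 1.5 times at Hoxb5 and Hoxb6 (1446 bases in replicate 1 and 263 in replicate 2), Hoxb9 (756 and 190), Hoxc5 (672 and 1175), Hoxd10 (419 and 261) and Hoxa10 (379 and 0), and Hoxb6 and Hoxa10 had no peak within 1 kb in replicate 2. Without a replicated peak within 1 kb were Hoxa6, Hoxa9, Hoxa11, Hoxb8, Hoxb13, Hoxc6, Hoxc8, Hoxc9, Hoxc11, Hoxc12 and Hoxd12. Among random lists matched on CpG ratio, this list lay at percentile 0 for marking and for coverage. Values of overlapping neighbours are not separate measurements: Hoxb5 and Hoxb6 share their covered bases, as do Hoxb7 and Hoxb8, Hoxd3 and Hoxd4 start side by side in the annotation, and the annotated Hoxc5 transcript spans Hoxc6, Hoxc8 and Hoxc9.

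**Figure D4:**
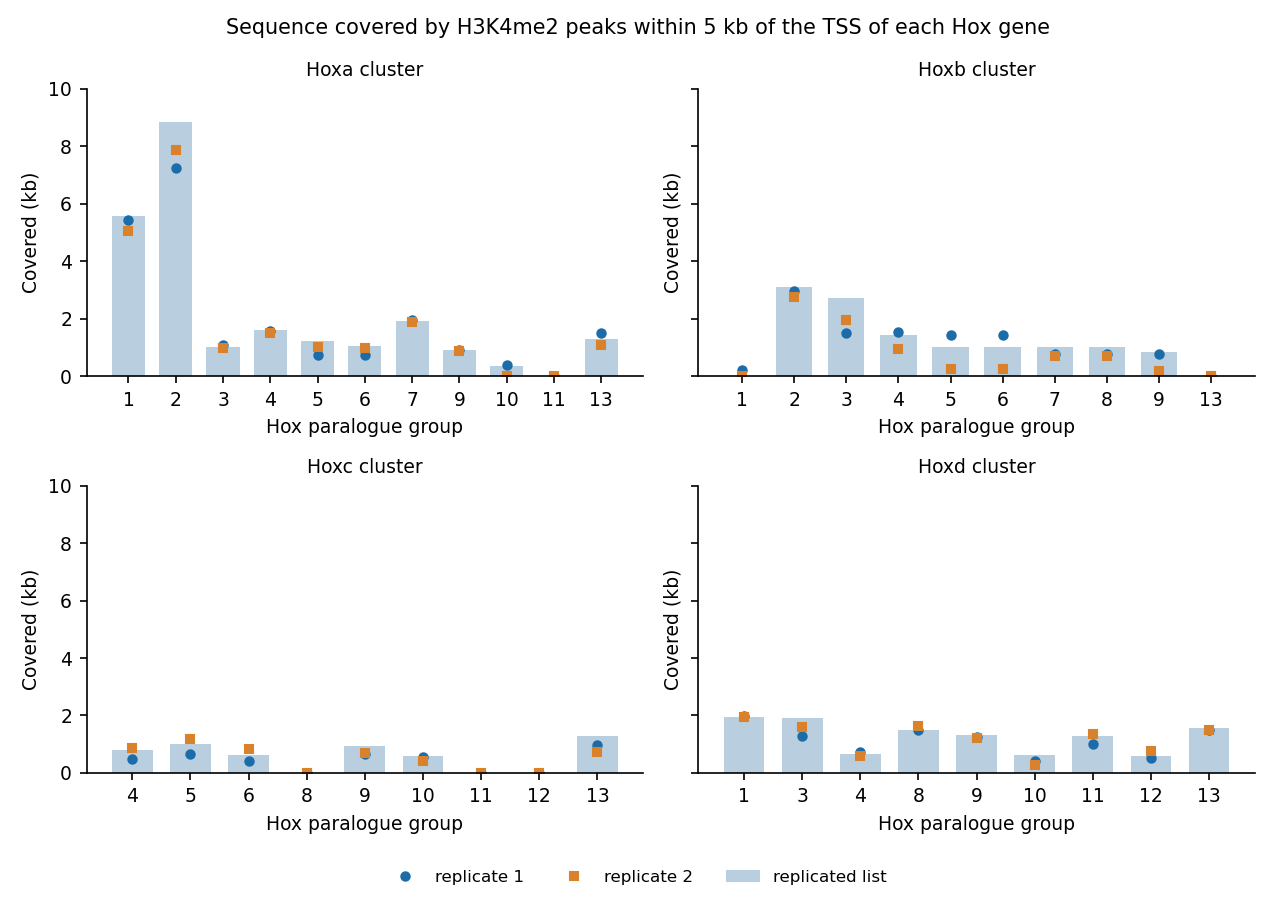
The sequence covered within 5 kb of the TSS is on the y axis in kb for every Hox gene of each cluster, by paralogue group on the x axis, with the replicated list as bars and the replicates as points. Hoxa2 (8848 bases) and Hoxa1 (5591 bases) stood above the other Hox genes, the next being Hoxb2 (3114 bases).

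Distal peaks were also numerous near facial genes, but the count includes parts of the blocks around TSSs that lie over 1 kb away. Alx1 had 10, while its mapped replicated peaks all lay between 103017727 and 103035944, around a gene start at 103030215. The count also depends on the distance to neighbouring genes, on which random lists were not matched: Dlx5 had 0 and the adjacent Dlx6 had 5. The gene with the most was Gse1 (31 replicated peaks, 59 in replicate 1 and 56 in replicate 2), followed by Zfhx3 (19, with 31 and 28 in the replicates). Cstad (26 and 17), Tbx3 (22 and 21) and Bcor (26 and 22) had 17 each, and Smad7 (26 and 18), Mecom (23 and 16) and Sox2 (20 and 17) had 16 each. By median number per gene, 7 of 19 lists lay above the bounds: facial transcription factors (5, percentile 100), forebrain and eye (4, 100), signalling (3, 100), heart (1.5, 99.7), epithelium (1, 97.9), skeletal muscle (1, 97.9) and neuron (1, 97.9). The replicates' own lists, which hold more distal peaks, gave medians of 8 and 7 for facial transcription factors, 2 and 1 for epithelium and cartilage, 2 and 1.5 for skeletal muscle and neuron, 1 and 1.5 for glia, and 1.5 and 2.5 for heart. A median of 1 was also that of endothelium (97.4), bone (96.3), Hox groups 1 to 4 (96.3), glia (95.5) and cartilage (95.4), within the bounds. Ties were counted at 50%, and lists with the same median differed in percentile only through their number of genes. The calls at a median of 1 therefore separate lists by size and not by their distal peaks. The median was 0 for the erythroid (42.4), macrophage (45.4), liver (43.5), germ line (42.4), Hox groups 5 to 13 (48.3), ribosomal protein (49.9) and olfactory receptor (50) lists. A median of 0 is the lowest possible and is also that of all genes, so no list could have lain below the bounds. These percentiles therefore decide nothing on a lack of distal peaks. With CpG-matched lists the facial, signalling and forebrain lists stayed at 100, epithelium (94.9) and neuron (94.6) came within the bounds, and bone (98.6) and glia (97.9) came above. Without replicate 1 epithelium lay at 93.1 and glia at 98.0, without replicate 2 heart lay at 97.0 and cartilage at 99.1, and with a reach of 250 kb skeletal muscle lay at 97.1 and epithelium at 97.1. Endothelium came above the bounds with −log10 p of at least 5 (97.8), a reach of 50 kb (98.3), replicated peaks that both replicates hold (98.6) and the pooled list (99.5), as did cartilage (99.96) and Hox groups 1 to 4 (99.0) with the pooled list.

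The widest domains without a protein-coding TSS within 1 kb lay partly over noncoding genes. The first, on chromosome 9 at 41578251 to 41589707, had 11154 bases under replicated peaks (replicates 10551.5 ± 165, SD, n = 2), lay 422 kb from the nearest protein-coding TSS, that of Ubash3b, and held the microRNA gene Mir125b-1. The second, on chromosome 13 at 63271727 to 63281865, had 9938 bases (9660 ± 181) in an intron of 2010111I01Rik. The third, on chromosome 13 at 23429107 to 23439465 near Abt1, had 9816 bases (9016.5 ± 250) and held the start of the long noncoding RNA gene C230035I16Rik. The fourth, on chromosome 19 at 5795793 to 5804587 near Scyl1, had 8612 bases (8439.5 ± 79.9) and held the start of Malat1, an abundant nuclear noncoding RNA. The fifth, on chromosome 19 at 12004677 to 12013803, had 8403 bases (7735 ± 102), with Olfr1423 as the nearest protein-coding gene at 27.5 kb.

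Across the genome, promoters were the class with the most peaks for their size. Of the replicated peaks, 43.2% (15256) had their midpoint within 1 kb of a protein-coding TSS (replicates 37.1% ± 2.87, SD, n = 2), a class that makes up 2.37% of the genome, an enrichment of 18.2 times. Promoter peaks had a median width of 1827 bases and held 60.1% of the covered bases. Exons held 5.88% of peaks (replicates 6.16% ± 0.210) against 2.93% of the genome, introns 23.8% (28.9% ± 1.69) against 33.5%, and intergenic sequence 27.2% (27.8% ± 0.974) against 61.2%. Of all 21853 protein-coding genes 67.0% (14638) had a replicated peak within 1 kb of a TSS (replicates 67.4% ± 0.275). Genes were split into 3 classes of equal size by the CpG observed/expected ratio within 500 bases of a TSS, the highest over the TSSs of the gene. In the lowest class 12.2% (891 of 7285) had a peak (replicates 13.3% ± 0.563), in the middle class 89.3% (6508 of 7284; replicates 89.6% ± 0.223), and in the highest class 99.4% (7239 of 7284; replicates 99.4% ± 0.0388). Median coverage within 5 kb was 0, 2067 and 2881 bases in these classes. The Wilson 95% interval of the lowest class began at 11.5%, that of the middle class ran from 88.6% to 90.0% and that of the highest from 99.2% to 99.5%, for counting error only.

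The only comparison between samples, replicate 1 against replicate 2, showed how far the pools shared their peaks. Of the replicate 1 peaks 68.6%, and of the replicate 2 peaks 77.6%, overlapped a peak of the other over at least 50% of either peak. Random rotations along the chromosomes gave a mean of 2.43% for replicate 1 and at most 2.73% in 100 rotations. The shared bases came to 40.3 Mb, 84.4% of the bases of replicate 1 and 87.6% of those of replicate 2, with a base-pair Jaccard index of 0.754 (0.0109 at most in the rotations). Sharing rose with the −log10 p that the authors gave each peak within its own list. Of peaks between 2 and 3 on that scale 17.2% were shared in replicate 1 and 26.2% in replicate 2, of those between 5 and 10 56.6% and 65.6%, and of those between 10 and 20 96.8% and 97.6%. Unshared peaks were narrow, with a median width of 227 bases in replicate 1 and 235 in replicate 2, against 990 and 979 for shared peaks. Coverage around TSSs in the replicates had a Pearson r of 0.978 and a Spearman rho of 0.968 across 15608 genes, which are not independent replicates.

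**Figure D5:**
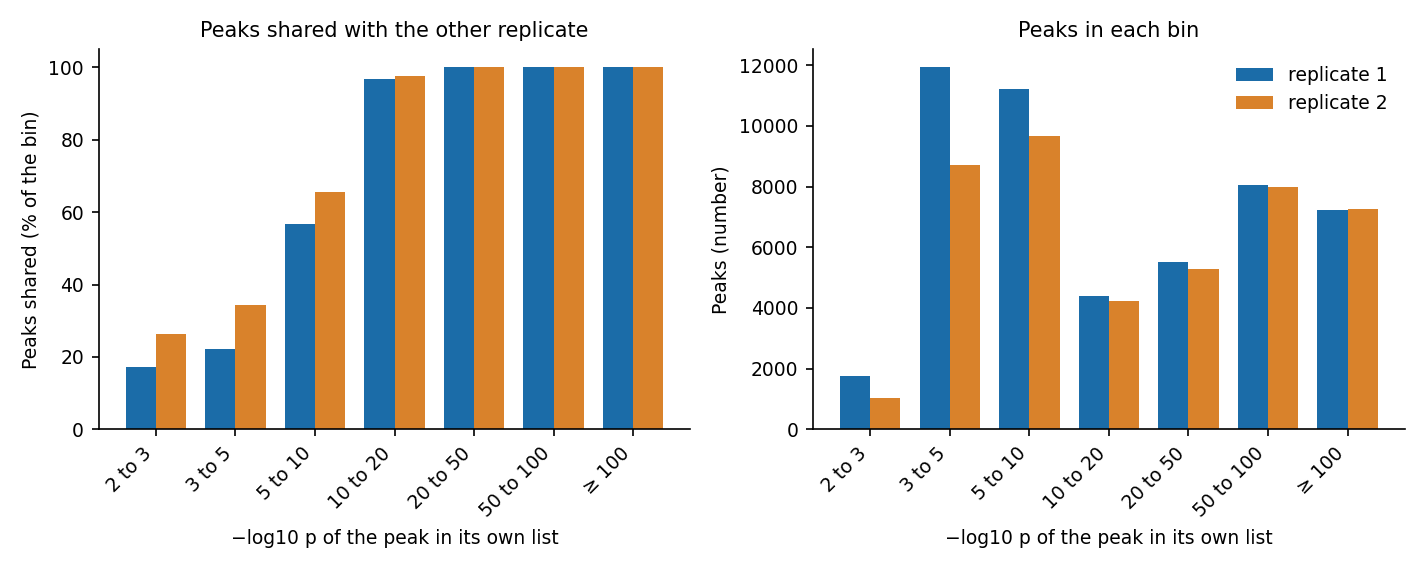
The percentage of each replicate's peaks that overlap a peak of the other replicate is plotted on the y axis against the −log10 p of the peak in its own list on the x axis. It was 17.2% for replicate 1 and 26.2% for replicate 2 between 2 and 3, and 96.8% and 97.6% between 10 and 20.

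At promoters, Tchh, which encodes the hair protein trichohyalin, Stap2, the homeobox gene Uncx, Tnnc1 and Ager were the genes with the most covered bases among those with a peak within 1 kb of a TSS in replicate 1 alone. Tmem253, Slc35g3, Iqcn, Amh (the anti-Müllerian hormone gene) and Synpo2l were those in replicate 2 alone. Uncx was covered over 3151 bases in replicate 1 and 1017 in replicate 2. For the other genes named, the coverage within 5 kb was closer, as for Tchh (4087 and 3859 bases) and Tmem253 (5341 in replicate 1 and 5991 in replicate 2). In all, 203 genes had such a peak in replicate 1 alone and 118 in replicate 2 alone, 14576 in both and 6956 in neither, so that the replicates gave the same state for 98.5% of genes. With the same number of peaks taken from each replicate, those with the highest −log10 p, the counts were 145 in replicate 1 alone and 145 in replicate 2 alone.

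The replicated list held a larger share of the pooled peaks near TSSs than of the distal peaks. Of the pooled peaks within 1 kb of a TSS 92.3% were in it, against 56.1% of the distal peaks. In total 69.1% of the pooled peaks were kept (35330 of 51153, Wilson 95% interval 68.7% to 69.5%, for counting error only and not for the spread between pools), with 92.5% of the pooled bases. The kept peaks had a median width of 1045 bases and a median −log10 p of 54.6, against 226 bases and 4.46 for the others. Peaks near TSSs and distal peaks of like strength were not compared, so location cannot be told apart from strength here. A rule that asks for an overlap of at least 50% of either peak in both replicates kept 31933 peaks, all of them in the list. It left 3397 listed peaks (9.62%), of which 1881 were touched by replicate 1 alone, 1279 by replicate 2 alone, 74 by both and 163 by neither. The rule behind the list is not given in the sources used here.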

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

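Of the tests in this part, the 2 on forebrain and eye genes were chosen only after the result was seen. Peaks on scaffolds not placed on a chromosome, which no comparison above used, numbered 15 in replicate 1, 14 in replicate 2, 16 in the pooled list and 14 in the replicated list. They were flagged because each count was above a limit of 3. Nothing in the design predicts a count of 0 on scaffolds, so passing this limit shows no excess. The peaks lay on 6 scaffolds, with 6 of them on 1 scaffold of chromosome X, some of these within 1 kb of Vamp7 or Tmlhe.

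The first pattern weighed was the wide coverage around the TSSs of facial mesenchyme transcription factor genes, a median of 8158 bases. Against the promoter CpG ratio as the whole cause, the median lay at percentile 100 among CpG-matched random lists. The match was on the ratio within 500 bases of a TSS, while coverage was counted within 5 kb. CpG content farther from the TSS was not matched, so the test decides nothing on it. Peaks of neighbouring genes were tested on the 42 of 45 genes with no other protein-coding TSS within 10 kb, whose median of 8271 bases, against 1678 for 14763 such genes, also lay at percentile 100. What stays open is whether the coverage is particular to the face, since no other tissue was sampled and no biological explanation was tested. Genes of other lists were as wide, such as Emx2 (9610 bases) and Six3 (8651 bases) of the forebrain and eye list and Fli1 (9312 bases) of the endothelium list. Whether these genes are also active in cells of the facial prominence was not tested, so their width does not settle the question.

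The second pattern was the lack of any peak at 15 macrophage and leukocyte genes. CpG-poor promoters were weighed with CpG-matched random lists, in which the share lay at percentile 2.07 with ties counted at 50%. The bound of 2.5 set in advance was unsuited to a share of 0, the lowest possible: 4.14% of the matched lists also had no marked gene, and on average 16.6% of their genes were marked. CpG content is therefore not excluded as the whole cause. A low share of such cells in the tissue, which would leave weak signal under the calling threshold, stays open and was not tested.

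The third pattern was a larger number of distal peaks in replicate 1 near forebrain and eye genes, 131 against 96, a log2 ratio of 0.45 beside 0.29 for all genes, with more in replicate 1 at 14 genes and more in replicate 2 at 1. Chance among genes could account for it, since the ratio lay at percentile 95.5 of random lists matched on peak counts. The larger number of weak peaks in replicate 1 could not be told apart from other sources: with the same number of peaks from each replicate the ratio still exceeded that of all genes by 0.21 on the log2 scale (112 against 96 peaks), at percentile 96.8, within the bounds. Among the other lists, cartilage lay above the bounds (61 against 39 distal peaks, more in replicate 1 at 9 genes and more in replicate 2 at 0, percentile 97.52, and 98.6 with the same number of peaks), as did olfactory receptors with the same number of peaks (42 against 28, percentile 98.0), where 0.95 of 19 lists would lie outside by chance. A difference in dissection between the pools was not tested, and no biological explanation was tested.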

How the results depend on the processing

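The alternatives were set before the data were examined, apart from keeping only replicated peaks that both replicates hold, which was chosen after seeing the data. Over 80 values and 668 recomputed values, 560 were the same, 22 weaker, 23 stronger, 61 moved and 2 reversed. For the gene lists, same means that no bound was crossed, weaker that the list came within the bounds, and stronger that it left them. Shifts inside the bounds thus count as same, as for bone marking with CpG-matched lists (percentile 4.09 to 67.7). The 2 alternatives for the named genes also count as same, although only 11 and 20 of the 28 genes stayed. The coverage of facial transcription factors (7360 to 8326 bases with the 5 kb window) and the number of their distal peaks stayed at percentile 100 in every alternative run. All 8 alternatives for the peaks per list and all 12 for the replicate-specific promoters stayed within 1.5 times the reported count. No paired analysis was possible because there was only 1 group. Where values below changed, the cause was not tested, except that CpG-matched lists change only the random lists and leave the value of the list itself as it was. Depth limits what a missing peak means, and it is unknown here.

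With CpG-matched random lists the marking of erythroid genes (35.7%) turned from below the bounds to percentile 85.4 and that of ribosomal proteins (96.2%) from above to 11.97, the only reversals. The ribosomal share fell short of 100% only through Rpl10l, Rpl39l and Rpl3l. Marking no longer passed for signalling (100%, percentile 94.6), epithelium (88%, 92.3) and neuron (94.4%, 92.0), and newly passed for cartilage (86.7%, 99.8), glia (90%, 99.98) and Hox groups 5 to 13 (59.3%, 0). The signalling share is the highest possible, and ties with its matched lists left no share that could pass, so its percentile decides nothing. Coverage no longer passed for erythroid (0 bases, 47.3), liver (0 bases, 28.1) and olfactory receptor genes (0 bases, 50), medians at the lowest possible value that tied with 94.5%, 56.1% and 100% of the matched lists, so that these percentiles decide nothing. It newly passed for Hox groups 5 to 13 (1008 bases, 0). Distal peaks no longer passed for epithelium (1, 94.9) and neuron (1, 94.6), and newly passed for bone (1, 98.6) and glia (1, 97.9).

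Without either replicate in turn, the promoter share ranged from 35.1% to 39.2%, marked genes in the lowest CpG class from 12.9% to 13.7% and in the highest from 99.37% to 99.42%. Coverage of Hoxa ranged from 17.4% to 17.6%, Hoxb from 4.59% to 6.29%, Hoxc from 3.57% to 4.04% and Hoxd from 12.5% to 13.2%. Marking of erythroid genes ranged from 35.7% to 42.9% (percentile 3.07 without replicate 2). Median coverage ranged from 2659 to 2735 bases for cartilage (97.2 without replicate 1), 0 to 277 for erythroid (4.15 without replicate 2), 0 to 0 for macrophage (2.38 and 2.17, below the bounds only with ties at 0 counted at 50%) and 2540 to 2569.5 for neuron (at the upper bound without replicate 1, which counts as passing). Distal peaks ranged from 1 to 2 for epithelium (93.1 without replicate 1), 1 to 2 for cartilage (99.1 without replicate 2), 1 to 1.5 for glia (98.0 without replicate 1) and 1.5 to 2.5 for heart (97.0 without replicate 2).

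With the pooled list the promoter share was 32.2%, marked genes in the lowest and highest CpG classes 14.9% and 99.5%, and coverage of Hoxa 21.03%, Hoxb 8.06%, Hoxc 4.97% and Hoxd 15.3%. Erythroid marking was 42.9% (percentile 2.8) and coverage 146.5 bases (2.97), both no longer passing. Coverage newly passed for macrophage (0 bases, 1.94, only with ties at 0 counted at 50%) and neuron (2844.5 bases, 97.6). Distal peaks newly passed for cartilage (3, 99.96), endothelium (2, 99.5) and Hox groups 1 to 4 (2, 99.0).

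With −log10 p of at least 5 the shared peaks were 81.7% of replicate 1 and 86.1% of replicate 2, pooled peaks in the replicated list 86.7%, pooled peaks kept by the overlap rule 69.7%, Hoxc coverage 2.90%, and endothelium distal peaks 1 (97.8, newly passing). With −log10 q of at least 2 the shared replicate 1 peaks were 76.8%, pooled peaks in the replicated list 75.8% and those kept by the rule 64.4%. With 50% overlap of both peaks the shared peaks were 57.7% and 65.4% and the rule kept 53.8%, and with an overlap of 1 base it kept 62.9%. With the same number of peaks from each replicate 75.5% of replicate 1 peaks were shared.

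With promoter windows of 500 bp the promoter share was 30.4%, marked genes in the lowest and highest CpG classes 10.8% and 99.3%, and epithelium marking 84% (97.2, no longer passing). With 2.5 kb these shares were 52.6%, 14.99% and 99.5%. With only the 5′-most TSS they were 35.5%, 10.4% and 99.2%, heart marking was 33.3% (1.85, newly passing), and coverage was 2714 bases for cartilage (96.7, no longer passing) and 2711 for neuron (98, newly passing). Marked genes in the middle CpG class then fell from 89.3% to 83.5%. With a coverage window of 10 kb the medians were 258.5 bases for erythroid (2.55) and 389.5 for germ line (3.16), no longer passing. They were 0 for macrophage (1.56, only with ties at 0 counted at 50%) and 3391.5 for forebrain and eye (99.3), newly passing. With a reach of 250 kb distal peaks no longer passed for epithelium (1, 97.1) and muscle (1, 97.1), and with 50 kb they newly passed for endothelium (1, 98.3). With only replicated peaks that both replicates hold, cartilage coverage was 2723 bases (96.1, no longer passing) and endothelium distal peaks 1 (98.6, newly passing).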

Other observations

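The gene families in this part were chosen only after the data were seen. Families of developmental transcription factors, some of whose members are also in the lists above, were marked widely. All 6 Irx genes had a peak, with a median of 7808.5 bases within 5 kb of the TSS (replicates 6908 ± 6.01, SD, n = 2), as had all 6 genes of the Six1 to Six6 family (7178 bases, replicates 6396 ± 215), and 8 of 9 Pax genes (6127 bases, replicates 5409 ± 82.0). All 19 Sox genes had a peak (3795 bases, replicates 3554 ± 89.1), with Sox6, Sox9 and Sox11 the most covered, and 39 of 44 Fox genes (3165.5 bases), with Foxf1, Foxd2 and Foxc1 the most covered. Each of these families lay at percentile 100 of random lists for coverage. All 8 Lhx genes had a peak (3184 bases, percentile 97.8), as had 11 of 13 Tbx genes (3192 bases, percentile 99.1). Zic (5 of 5 genes, 3360 bases, percentile 95.7) and Gata (5 of 6 genes, 2887 bases, percentile 91.5) lay within the bounds.

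Guidance and matrix genes were also widely covered, and the keratin, cytochrome P450, defensin and vomeronasal receptor families were not. All 14 Eph receptor genes (3238.5 bases, percentile 99.6) and all 20 semaphorin genes (3220 bases, percentile 99.9) had a peak, and so had 38 of 44 collagen genes (2895.5 bases, percentile 100), with Col12a1 and Col2a1 the most covered. Of the ligand families, 18 of 19 Wnt genes (2721 bases, percentile 97.4) and 20 of 22 Fgf genes (2504 bases, percentile 94.1) had a peak, with both families within the bounds for coverage. Potassium channel genes (75 of 92, 1740 bases, percentile 23.2) and solute carrier genes (246 of 334, 1824 bases, percentile 23.4) lay within the bounds. Keratin genes (7 of 49, among them Krt8 and Krt18 of the epithelium list, percentile 0.09), cytochrome P450 genes (26 of 93, percentile 0), defensin genes (0 of 42, percentile 0.105) and vomeronasal receptor genes (1 of 327, percentile 0) had a median of 0 bases. Among the cytochrome P450 genes Cyp26b1 and Cyp26a1, which encode enzymes that break down retinoic acid, were the most covered. Families were not matched on CpG ratio.

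By chromosome, 68.2% of 20722 autosomal genes had a replicated peak within 1 kb of a TSS, 52.2% of 948 genes on X and 2.19% of 183 genes on Y, with 968 replicated peaks on X and 5 on Y.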
